A study of Homo sapiens with 6 samples.

How the data were processed

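RNA from 6 cultures of BT549 cells with an inducible miR-200c construct was measured, 3 left untreated and 3 kept in doxycycline. Per the labels, cells grew attached in RPMI medium with 10% serum, RNA was extracted with an RNeasy Plus kit, and 1 µg of total RNA per sample was labelled with FlashTag biotin. That kit is usual for microRNA arrays, while the table holds exon regions and junctions, so how the RNA behind these intensities was labelled is not settled by the sources used here. The deposited values are log2 intensities, one per probe set and array, and per the submitters' processing notes Partek was used, with no role or version named. Background correction, normalization, summarisation and genome build are not given in the sources used here. That the scale is log2 was read from the range of the values. The form of the row names is that of an Affymetrix human transcriptome array, with exon regions (PSR names) and exon junctions (JUC names). No coordinates are printed, since the array's build is not named.

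The table held 925032 rows, of which 345 were control rows and 924687 were tested. By the platform annotation, 672085 rows had 1 gene symbol, 39483 had several and 213119 had none. Gene-level values were the mean log2 over the rows with exactly 1 symbol, giving 22085 genes with a median of 23 rows each, of which 2694 had a single row. The symbols are those of the annotation, which can be old; 22014 matched a current symbol or a unique synonym in the RefSeq table, and 2474 of them through a synonym. ZEB2 (101 rows) and TUBB3 (48 rows) were named only on rows that name another gene too, so no value is given for them, and CTNND1 is left out for the same reason. Column medians differed by at most 0.03, within the tolerance of 0.1 set before the data were examined, so the deposited values were used without further normalization. The 23 background rows had values from 4.10 to 6.36 with a median of 4.55, and a mean under 6.36 is described as within the background range. For a gene this is the mean over its rows, single rows of which can lie above the range. Between any 2 arrays at most 0.00692% of values were equal, so no array was a copy of another.

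All fits used the 6 arrays with the group as the single term, in limma 3.58.1 under R 4.3.3. Files were read with the data.table package (version 1.17.8) and figures were drawn with matplotlib 3.10.9. Genes and rows were tested with lmFit and eBayes and Benjamini-Hochberg adjustment, with a threshold of 0.05. Lists of genes were tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, and with fry. Lists could share genes: 23 of 51 measured miR-200 targets, 20 of 45 immunosuppression genes and 13 of 36 NF-kappaB targets were also in other lists. Of 31 lists fixed from general knowledge before the data were examined, 30 had at least 5 measured members; of the list of mitochondrially encoded mRNAs 0 genes were measured here. In all 19 lists passed with the preset correlation, 0 with an estimated one and 18 with fry, and the fry calls included the integrin and laminin list and the splicing list. Of the 18 lists 16 were among the 19. The DNA replication, respiratory chain and mitochondrial ribosome lists did not pass with fry. Genes with at least 3 rows brighter than the median row were tested for uneven change with diffSplice's F-test, and, as an addition, with each row taken relative to its gene's mean on each array, its own variance and a Simes p per gene. A test of genes with a miR-200c seed site was not run, since no 3' UTR sequence was used here.

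On simulated data built on the comparison's 22085 genes, with 50 genes changed at each size, the gene-level fit recovered 86% of changes of 0.25, 98% of 0.5 and 100% of 1 and of 2, with 9 false calls. A list of 30 genes shifted by 0.2 was recovered, with 0 unshifted lists called. Genes were drawn independently there, so the simulation cannot show false list calls from genes that vary together. On the arrays, splits that mix the groups gave from 4 to 14 lists at the preset correlation. For uneven change over 15773 genes with 200 changed in 1 row by 2, the F-test recovered 100% with 215 false calls, and the test with own variances 94% with 9 false calls.

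Genes were named by a rule fixed before the data were examined. It took MIR200C, ZEB1, CDH1, VIM, FN1, QKI, MSN, TDO2, KYNU, CD274, PDCD1LG2, HMOX1 and GDF15 whatever their result, and the 10 largest rises and 10 largest falls among genes past the threshold, with groups that do not overlap and at least 3 rows. Symbols of the LOC, LINC, MIR, SNOR, RNU, RNA5 and OR kinds, antisense names and names ending in P and digits were left out of those 20, which excludes ESRP1 there. It also took up to 4 members of each list with the smallest p past the threshold, or 2 where none passed, and for uneven change the 6 smallest p with CD44, FGFR2 and ENAH. Members that moved against their list, and the genes named in the closing section beyond these, were chosen after their values were seen. Not all genes the rule allows are printed.

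Alternatives were other scalings, the median over a gene's rows, filters on dim rows and genes, other variance settings and thresholds, the letters of the labels as a block, other set tests, and each array left out in turn. The arrays' background as a covariate, the fit without untreated replicate B and treated replicate A, the rows above 8 and the own-variance test were added after the data were examined.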

Results

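Gene expression was measured in BT549 cells, an established human cell line from a triple-negative breast cancer with mesenchymal features, carrying a doxycycline-inducible construct for the microRNA miR-200c. Members of the miR-200 family are known as repressors of the transcription factors ZEB1 and ZEB2 and as guardians of the epithelial state. Total RNA from 3 untreated cultures and from 3 cultures kept in 1 µg/mL doxycycline for 48 h was hybridised to 1 array each, so that n = 3 per group. The cultures were plated in triplicate and described as biological replicates. Whether the replicate letters A, B and C mark plates or days is not known, so SDs and p-values describe the spread between these cultures. Each array gave 924687 log2 intensities, of which 575209 were for exon regions, 341494 for exon junctions and 7984 for other rows, and the mean over the rows naming a single gene gave values for 22085 genes. Median log2 intensity ranged from 5.18 to 5.21 across the 6 arrays, and the lowest correlation between any 2 arrays over genes was 0.994. The first principal component, with 61.1% of the variance, separated the treated from the untreated arrays. All treated cultures received doxycycline and carried the construct, so the drug and the microRNA cannot be told apart in these arrays. The precision of every value is limited by the number of arrays, and differences are given as treated minus untreated.

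The comparison asks which transcripts change when miR-200c is switched on in these cells. The row for MIR200C rose from 4.96 ± 0.26 to 9.53 ± 0.024 (SD, n = 3), a log2 change of 4.57 with an SE of 0.11 and an adjusted p of 2.75e-07 in limma. Its untreated mean lay within the range of the arrays' background rows, which reached 6.36, and set against the top of that range the rise was at least 3.17, or 8.99-fold. Whether this single row measures the mature microRNA or a longer transcript is not given in the sources used here. ZEB1, the repressor of epithelial genes, fell by 0.77 on the log2 scale (from 7.49 ± 0.044 to 6.72 ± 0.023, adjusted p = 1.07e-05). The RNA-binding protein gene QKI fell by 1.31 (from 9.71 ± 0.073 to 8.40 ± 0.028, adjusted p = 1.53e-06). SEC23A, which encodes a component of the vesicle coat that carries cargo out of the endoplasmic reticulum, fell by 1.14 (adjusted p = 1.30e-06), and the phospholipase gene PLCG1 fell by 0.80 (adjusted p = 1.18e-05).

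Among 51 measured genes of a list of studied miR-200 family targets, 23 fell, 3 rose and 25 did not pass the test. Adjusted over the list alone, 26 fell and 4 rose. The 3 that rose were CDKN1B, EPHA2 and ERBB2IP, an inhibitor of cyclin-dependent kinases, a receptor tyrosine kinase and a scaffold protein of the basolateral membrane. The median log2 change of the list was -0.10, with an adjusted p of 4.17e-12 by limma's camera test at a preset correlation, and adjusted p = 0.0701 with an estimated correlation. FN1, which encodes fibronectin, fell by 0.41 (from 8.97 ± 0.076 to 8.56 ± 0.031, adjusted p = 7.68e-04). Moesin (MSN) had a log2 change of -0.10 with an adjusted p of 0.207, and did not pass. With the median of a gene's rows in place of the mean, ZEB1 had a log2 change of -0.51 and an adjusted p of 0.0784.

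**Figure D1:**
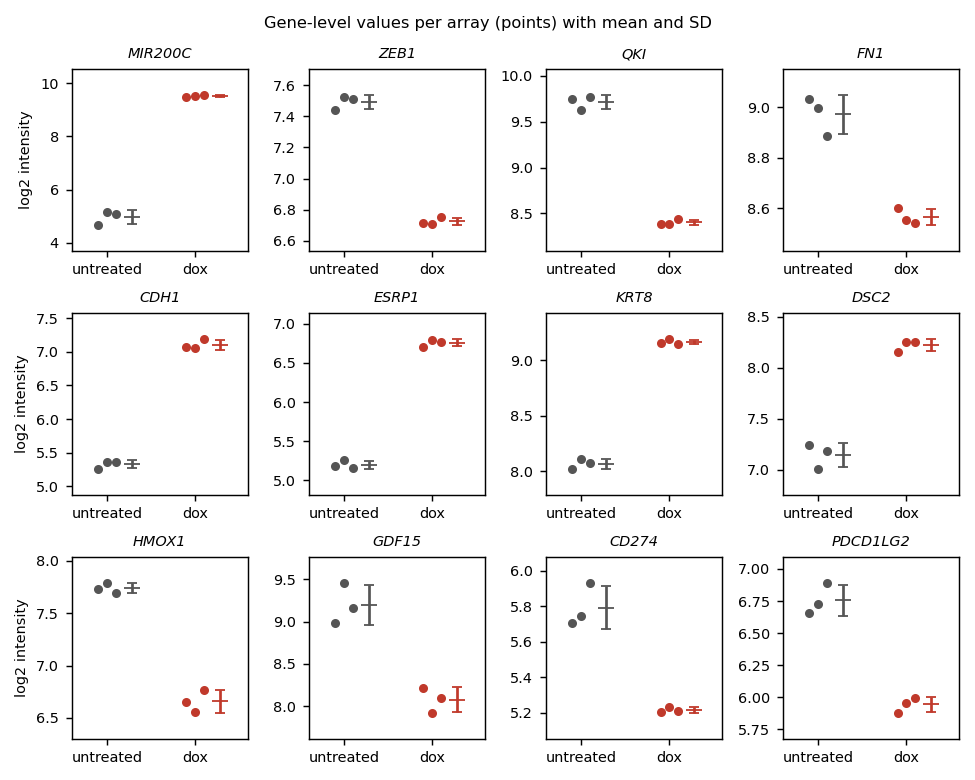
Log2 intensity of 12 genes on each array (points), with the mean and SD of the 3 arrays per group beside them, for untreated cultures (grey) and cultures in doxycycline (red), each panel with its own axis. The measured changes of MIR200C and CDH1, both from an untreated mean within the background range, were 4.57 and 1.77, while HMOX1 fell by 1.08, and in every panel the groups' arrays did not overlap.

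Many genes of epithelial junctions were higher in doxycycline. CDH1, which encodes the adherens junction protein E-cadherin, went from 5.33 ± 0.059 to 7.10 ± 0.073 (SD, n = 3), a measured log2 change of 1.77 (SE 0.05, adjusted p = 5.92e-07). Its untreated mean lay within the background range, and set against the top of that range the treated level was at least 1.67-fold higher. ESRP1, an epithelial splicing regulator, rose by a measured 1.56 (adjusted p = 5.33e-07), also from a mean in the background range, and by at least 0.40 against its top. CDS1, an enzyme of phospholipid synthesis, rose by 1.68 (adjusted p = 1.53e-06), and the polarity scaffold gene INADL, now named PATJ, rose by a measured 1.49 (adjusted p = 2.30e-07), and by at least 0.87 against the top of the background range. Of 54 measured genes of epithelial adherens and tight junctions and keratins, 22 rose and none fell, and 23 rose when adjusted over the list alone. The list's camera test gave an adjusted p of 1.72e-12, and adjusted p = 0.132 with an estimated correlation. In 38 of the 54 genes both group means lay in the background range. A mean over rows in that range does not place every row there, and here the range is set beside means unless rows are named.

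In a list of desmosome, hemidesmosome and gap junction genes 8 of 18 rose, none fell and 10 did not pass. The risen genes were desmosomal or hemidesmosomal, and none of the gap junction genes GJA1, GJB2 and GJB5 passed over all genes (log2 changes -0.10, 0.06 and -0.03). Adjusted over the list alone 9 rose and 1, GJA1, fell (camera adjusted p = 5.34e-07, and adjusted p = 0.0701 with an estimated correlation). The desmosomal cadherin genes DSC2, DSC3 and DSG2 rose by 1.08, 1.02 and 0.85, and JUP, which encodes plakoglobin, by 0.52 from a mean within the background range, or at least 0.13 against its top. Luminal breast markers included 5 genes of 20 that rose and none that fell, and the counts were the same when adjusted over the list alone (camera adjusted p = 0.00168, and adjusted p = 0.314 with an estimated correlation). The keratin genes KRT8 and KRT18 rose by 1.10 and 0.52. MUC1, a membrane mucin gene, rose by 0.70 from a mean within the background range, or at least 0.58 against its top, and with the median of its rows the change was 0.18 with an adjusted p of 0.473. Of 19 basal markers 7 rose and none fell, with the same counts adjusted over the list alone (camera adjusted p = 2.40e-05, and adjusted p = 0.145 with an estimated correlation). These included SFN (log2 change 0.50 from a mean within the background range, but at least 1.01-fold against its top), ITGB4 (0.44, with both means in that range but 28 of its 91 rows above it in doxycycline) and CDH3 (0.32). The own-variance test for uneven change called each of these genes. In SFN 1 of 10 rows rose, and in CDH3 5 rows rose and 2 fell. Of the 28 rows of ITGB4 4 had changed, and 18 were above the range untreated too. KRT5 rose by 0.46 with both means in the background range, and with the median of its rows the change was 0.31 with an adjusted p of 0.103.

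A part of the mesenchymal genes fell, and vimentin did not pass the test. VIM had a mean of 10.46 ± 0.063 untreated and 10.37 ± 0.011 treated (SD, n = 3), with an adjusted p of 0.213 in limma. The matricellular protein gene POSTN fell by 0.99 to a mean within the background range (at least 0.97 against its top, adjusted p = 1.42e-04), and the protease gene FAP fell by 0.56 with both means in the background range (adjusted p = 1.61e-04). The lysyl oxidase gene LOX, whose product crosslinks collagen, fell by 0.71 (adjusted p = 2.83e-05), and with the median of its rows the change was -0.97 with an adjusted p of 0.0780. Of 54 measured mesenchymal genes 18 fell, and 20 did when adjusted over the list alone; 2 rose under both adjustments, WNT5A and CDH2, a secreted signalling ligand and N-cadherin (camera adjusted p = 3.47e-10, and adjusted p = 0.132 with an estimated correlation).

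Genes of collagens and their modifying enzymes fell in 9 of 33 cases, or 12 adjusted over the list alone, and 1 rose under both adjustments (camera adjusted p = 9.30e-07, and adjusted p = 0.0701 with an estimated correlation). COL1A1 fell by 0.38 and CRTAP, part of the collagen prolyl hydroxylation complex, fell by 0.51. The gene that rose was COL8A1, by 0.27 with both means in the background range, and with the median of its rows the change was 0.05 with an adjusted p of 0.789. Integrin and laminin subunits went both ways, with 6 lower and 3 higher of 26, or 6 lower and 6 higher adjusted over the list alone. The list did not pass by camera (adjusted p = 0.198) but did by fry (adjusted p = 0.0298). ITGA4 and ITGA5 fell by 0.45 and 0.40. Of 56 regulators of actin dynamics 10 rose and 10 fell, with 10 and 14 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.452). FHOD1 and CFL2, which encode a formin and a cofilin, fell by 0.53 (both means in the background range) and 0.55, while SSH3, a cofilin phosphatase gene, rose by 0.41. In the TGF-beta pathway 6 genes of 31 rose and 4 fell, with 10 and 7 adjusted over the list alone (camera adjusted p = 0.280, not passing). LTBP1, which encodes a latent TGF-beta binding protein, fell by 0.68 (adjusted p = 1.18e-05).

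Some genes for immunosuppressive factors fell, several of them from low mean levels. HMOX1, which encodes heme oxygenase, fell by 1.08 (from 7.74 ± 0.045 to 6.66 ± 0.11, adjusted p = 1.65e-05), and GDF15, a secreted stress cytokine gene with 3 rows, fell by 1.12 (from 9.20 ± 0.24 to 8.08 ± 0.15, adjusted p = 5.76e-04). The checkpoint ligand gene PDCD1LG2 fell by 0.81 (from 6.76 ± 0.12 to 5.94 ± 0.061, adjusted p = 1.12e-04), to a mean in the background range, and by at least 0.39 against its top. CD274, which encodes PD-L1, fell by 0.58 (from 5.79 ± 0.12 to 5.22 ± 0.016, adjusted p = 4.38e-04), with both means in the background range. The chemokine gene IL8, now CXCL8, fell by 1.04 and the cytokine gene LIF fell by 0.80. Of 45 genes of the immunosuppression list 14 fell and 3 rose, with 20 and 6 adjusted over the list alone (camera adjusted p = 4.82e-06, and adjusted p = 0.255 with an estimated correlation). The risen genes were ARG2, INHBA and LGALS3, an arginase, an activin subunit and a galectin. The list and the next one include genes known from work on this cell system, so their counts are not independent evidence of direction.

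Of 21 genes of tryptophan catabolism and transport 4 fell and none rose, with 6 lower and 3 higher adjusted over the list alone (camera adjusted p = 0.0336, and adjusted p = 0.255 with an estimated correlation). KYNU, which encodes kynureninase, fell by 0.42 (from 7.52 ± 0.11 to 7.10 ± 0.10, adjusted p = 0.00502). TDO2, the gene for tryptophan dioxygenase, fell by 0.24 from 4.93 ± 0.090 to 4.70 ± 0.042 (adjusted p = 0.0198), both means within the background range. IDO1, another dioxygenase gene, fell by 0.21 with both means in that range (adjusted p = 0.0302) and KMO, the kynurenine monooxygenase gene, by 0.32 (adjusted p = 0.0281). With the median of their rows none of these passed, with changes of -0.74 for KYNU (adjusted p = 0.132), -0.24 for TDO2 (0.0979), -0.28 for IDO1 (0.210) and -0.21 for KMO (0.621), and with brighter rows alone TDO2 changed by -0.17 (0.319). Without treated replicate B the adjusted p was 0.0721 for the list (0.155 with brighter genes alone), 0.0867 for TDO2, 0.0969 for IDO1 and 0.111 for KMO. Of the 6 fits with 1 array left out, calls were lost in 5 for IDO1, 4 for KMO, 3 for TDO2, 2 for the list and 0 for KYNU.

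Interferon-stimulated genes had the largest share of fallen members among the 30 lists tested. Of 41 measured genes 29 fell and none rose, and 36 fell when adjusted over the list alone. The median log2 change was -0.37, with a camera adjusted p of 4.28e-22 and adjusted p = 0.255 with an estimated correlation. XAF1 fell by 0.67 (from 8.12 ± 0.12 to 7.44 ± 0.10, adjusted p = 5.26e-04), GBP1, which encodes a guanylate-binding protein, fell by 0.54 and SP110 fell by 0.40. SAMD9 fell by 0.61, and with the median of its rows the change was -0.66 with an adjusted p of 0.0820. The mean over the list was 7.96, 8.18 and 8.21 on the untreated arrays A, B and C and 7.74, 7.69 and 7.78 on the treated ones.

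Of 36 targets of NF-kappaB 16 fell and none rose, and 24 fell adjusted over the list alone (camera adjusted p = 9.79e-13, and adjusted p = 0.145 with an estimated correlation). The fallen genes IL8, LIF, IL6 and IL1B are also in the immunosuppression list, so the falls of these lists are not separate findings. IRAK2, a kinase gene of interleukin-1 receptor signalling, fell by 0.52, and SOD2, the mitochondrial superoxide dismutase gene, fell by 0.42. Of 20 genes of MHC class I antigen presentation 4 fell and none rose, and 8 fell adjusted over the list alone (camera adjusted p = 3.45e-04, and adjusted p = 0.313 with an estimated correlation). The peptide transporter gene TAP2 fell by 0.27 (adjusted p = 0.00644). Its partner TAP1 fell by 0.29 (adjusted p = 0.0155). HLA-B fell by 0.20 and HLA-C fell by 0.24. With the median of their rows the changes were -0.39 for TAP1, -0.41 for HLA-B and -0.39 for HLA-C, with adjusted p of 0.150, 0.275 and 0.209. Without treated replicate B they were -0.27 for TAP1 and -0.16 for HLA-B, with adjusted p of 0.0711 and 0.0858. Of the 6 fits with 1 array left out, TAP1 lost its call in 1 and HLA-B in 4.

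**Figure D2:**
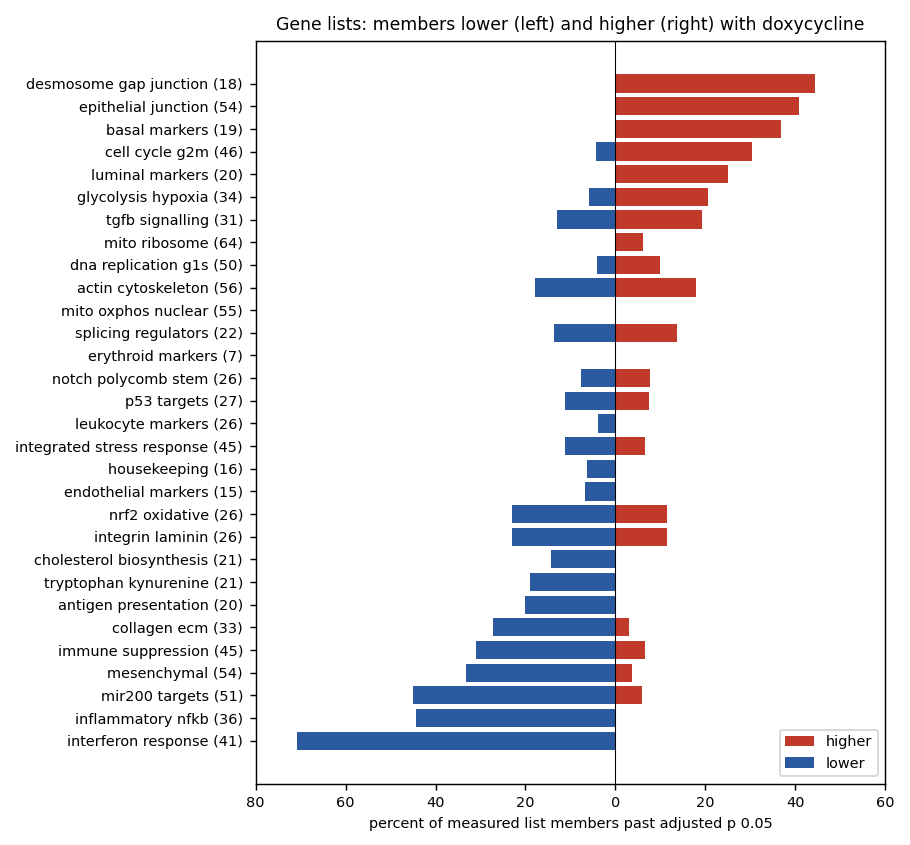
Percent of the measured members of each of 30 gene lists that were higher (red, right) or lower (blue, left) in doxycycline at an adjusted p under 0.05, with the number of measured members in parentheses. The interferon list had 29 lower members of 41, and the epithelial junction list 22 higher of 54.

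Some mitotic genes rose, by small amounts. Of 46 G2 and mitosis genes 14 rose and 2 fell, with 23 and 2 adjusted over the list alone, and the median log2 change was 0.15 (camera adjusted p = 3.35e-10, and adjusted p = 0.305 with an estimated correlation). CDC25C, the mitotic phosphatase gene, rose by 0.26, NUSAP1 by 0.23, CCNB2 by 0.22 and KIF20A by 0.20, and with the median of their rows the changes were 0.38, 0.24, 0.20 and 0.24, with adjusted p of 0.239, 0.239, 0.105 and 0.0661. Among 50 genes of G1/S and DNA replication 5 rose and 2 fell, with 6 and 2 adjusted over the list alone (camera adjusted p = 0.00153, and adjusted p = 0.528 with an estimated correlation). E2F8 rose by 0.34 and CDCA7 fell by 0.26, and with the median of their rows the changes were 0.43 and -0.29 with adjusted p of 0.407 and 0.527. Without untreated replicate B that list had an adjusted p of 0.0547, and 0.0820 with brighter genes alone. With fry its adjusted p was 0.161.

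The glucose transporter gene SLC2A1 rose by 0.56 (adjusted p = 3.80e-05) and the peptide hormone gene ADM rose by 0.41, and 7 genes of the 34 for glycolysis and hypoxia rose while 2 fell, or 8 and 2 adjusted over the list alone (camera adjusted p = 0.00920, and adjusted p = 0.425 with an estimated correlation). That list had an adjusted p of 0.0898 with the median of a gene's rows and 0.113 with brighter genes alone. In sterol synthesis 3 genes of 21 fell and none rose, with 7 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.00208, and adjusted p = 0.305 with an estimated correlation). HMGCS1, an enzyme gene early in that pathway, fell by 0.55 (adjusted p = 1.60e-04). Of 26 NRF2 targets 6 fell and 3 rose, with 7 and 3 adjusted over the list alone (camera adjusted p = 0.0135, and adjusted p = 0.425 with an estimated correlation). The drug transporter gene ABCC1 rose by 0.46 while HMOX1 fell by 1.08, and the list had an adjusted p of 0.0984 without treated replicate B, 0.0739 with the median of a gene's rows and 0.0820 with brighter genes alone. None of 55 nuclear genes of the respiratory chain passed under either adjustment, overall or adjusted over the list alone, while the list shifted up by a median of 0.04 (camera adjusted p = 0.0230, and adjusted p = 0.381 with an estimated correlation). UQCRFS1 (0.18, adjusted p = 0.0513) and COX5A (0.15, adjusted p = 0.0528) had its smallest p-values, and the list had an adjusted p of 0.222 without untreated replicate C, 0.242 with the median of a gene's rows and 0.290 with brighter genes alone. With fry the list had an adjusted p of 0.0947. Of 64 mitochondrial ribosome genes 4 rose and none fell, with 3 higher adjusted over the list alone (camera adjusted p = 0.0107, and adjusted p = 0.313 with an estimated correlation). Without treated replicate C its adjusted p was 0.0733, and 0.220 with brighter genes alone. With fry it was 0.0586.

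Stress, p53, Notch and splicing programmes did not pass as lists by camera. Among 45 ATF4 and CHOP targets 3 rose and 5 fell, with 5 and 7 adjusted over the list alone (camera adjusted p = 0.846), and their median of 0.01 and mean of -0.03 differed in sign. VLDLR, a lipoprotein receptor gene in that list, fell by 1.05 (adjusted p = 3.45e-06). Of 27 p53 targets 2 rose and 3 fell, with 3 and 5 adjusted over the list alone (camera adjusted p = 0.280), among them DDB2, a DNA repair gene, which rose by 0.39. Of 26 Notch and polycomb genes 2 rose and 2 fell, with 2 and 3 adjusted over the list alone (camera adjusted p = 0.846), and the Notch ligand gene JAG2 rose by 0.45 with both means in the background range. Among 22 RNA-binding regulators of splicing 3 rose and 3 fell, with 3 and 4 adjusted over the list alone (camera adjusted p = 0.946, while fry gave an adjusted p of 0.00570). These included the fall of QKI and the rises of ESRP1 and of RBM47, by 0.65 with both means in the background range.

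Markers of other cell types mostly had means in the background range. Of 26 leukocyte markers 25 had both means in that range, and the exception, the lysosomal gene CD68, fell by 0.70 from 8.34 ± 0.10 to 7.64 ± 0.19 (adjusted p = 0.00169). It was the only member to pass, overall and adjusted over the list alone (camera adjusted p = 0.231). Of 15 endothelial markers 1 passed under both adjustments, the TGF-beta co-receptor gene ENG, which fell by 0.49 (camera adjusted p = 0.333). None of 7 erythroid markers passed under either adjustment, overall or adjusted over the list alone (camera adjusted p = 0.846), and HBD and SLC4A1 had log2 changes of -0.05 and 0.04. Of 16 reference genes GUSB alone passed, with a log2 change of -0.24 and an adjusted p of 0.0434, and none did adjusted over the list alone (camera adjusted p = 0.626). The change was -0.24 with an adjusted p of 0.0640 with array medians subtracted, and -0.19 with 0.146 without treated replicate B. GUSB lost its call in 5 of the 6 fits with 1 array left out.

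Across all 22085 genes 2187 changed at a Benjamini-Hochberg adjusted p under 0.05 in limma, 1338 of them higher and 849 lower in doxycycline, and 4812 had an unadjusted p under 0.05. Most changes were small, with a median size of 0.24 on the log2 scale, and 20 of the higher and 9 of the lower genes changed at least 2-fold. In 557 of the changed genes both group means lay within the background range, although 493 of these had at least 1 row above it in a group and 252 had a changed row above it. The groups did not overlap in 26.0% of all genes, where chance gives 10%.

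The largest measured rises among genes with at least 3 rows were those of the transcription factor SOX15 (1.90, SE 0.08, adjusted p = 3.45e-06), the adhesion receptor GPR126, now ADGRG6 (1.83, SE 0.04, adjusted p = 2.30e-07) and CDH1. The untreated means of GPR126, CDH1, EPHA3 and INADL lay within the background range, so their sizes and order are those of the measured values, and set against its top GPR126 rose by at least 1.08 and EPHA3 by at least 0.75. FAM83B rose by 1.69, the ephrin receptor gene EPHA3 by 1.58, the prostacyclin synthase gene PTGIS by 1.27, and PLCB4 and EXPH5 by 1.14 each, the last with both means in the background range but 9 of its 26 rows above it in doxycycline. The largest falls were those of OSTM1, a lysosomal membrane protein gene (fell by 1.62, SE 0.06, adjusted p = 2.67e-06) and KDELC1, now POGLUT2, a protein glucosyltransferase gene (fell by 1.44, SE 0.06, adjusted p = 3.45e-06). They were followed by QKI, SEC23A, GDF15, HMOX1, VLDLR and IL8. LHFP, now LHFPL6, and POSTN each fell by 0.99. With the median of a gene's rows 696 genes passed in all, of which 643 were among the 2187, and without treated replicate B 1307 passed.

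**Figure D3:**
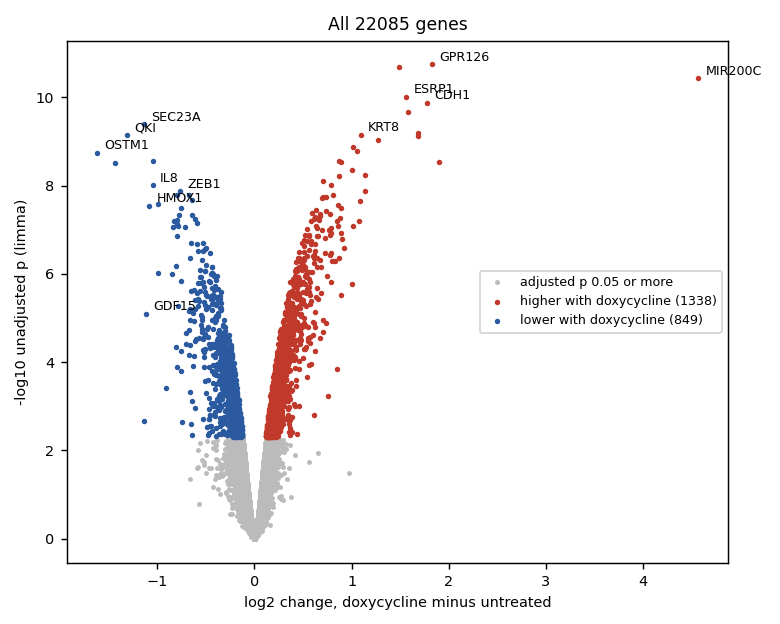
Log2 change, treated minus untreated, against the negative log10 of the unadjusted limma p for 22085 genes, with 1338 higher (red) and 849 lower (blue) genes at an adjusted p under 0.05. MIR200C lies farthest to the right at a measured 4.57, from an untreated mean within the background range, and OSTM1 farthest to the left at -1.62.

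Single exon regions and junctions were tested as well, since the miR-200 targets include splicing regulators. Of 924687 rows 6729 changed, 4167 higher and 2562 lower, and 93771 had an unadjusted p under 0.05. Exon regions made up 4337 of the changed rows and exon junctions 2381. Without treated replicate B 1614 rows passed, and the counts without each other array lay up to 3570.

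Several genes changed unevenly along their length. In DST, which encodes a cytoskeletal linker, 4 rows rose and 9 fell, with row changes from -2.17 to 3.25, while its mean change of 0.15 did not pass (adjusted p = 0.104). In MACF1, another linker of actin and microtubules, 48 rows rose and 4 fell. MARK3, a microtubule-affinity kinase gene, had 5 rows that fell and 1 that rose, with row changes from -3.49 to 1.16. In KIF1B, a kinesin motor gene, 40 of 103 rows rose and none fell, and the median row change was 0.18. INADL and the collagen receptor gene DDR1 had 63 of 84 and 95 of 265 rows higher, and none lower. Where rows moved in a single direction, as in KIF1B, INADL and DDR1, compression in dim rows of a gene that changed as a whole could give the same call. These genes had the smallest p-values of limma's F-test, by which 1592 of 15773 genes changed unevenly, and 752 of those had not passed the test in their mean. ENAH, an actin regulator gene with an epithelial exon, had an adjusted p of 0.0283 in that test. In ENAH 1 row fell and none rose, and whether that row lies on the epithelial exon was not determined. CD44 (adjusted p = 0.151) and FGFR2 (adjusted p = 1) did not pass the F-test.

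The F-test was liberal on simulated data, where 200 genes with 1 changed row came with 215 false calls. Its count on the arrays was 644 without treated replicate C, 830 without treated replicate B, 1008 without untreated replicate A and 3863 without treated replicate A, and a split of the arrays that mixes the groups gave 3962. A test with each row's own variance, added after the data were examined, called 116 genes, all among the 1592. It called INADL (adjusted p = 0.00337), MARK3 (0.00476), KIF1B (0.00945), DST (0.0174) and MACF1 (0.0229), but neither DDR1 (0.106) nor ENAH (0.163).

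**Figure D4:**
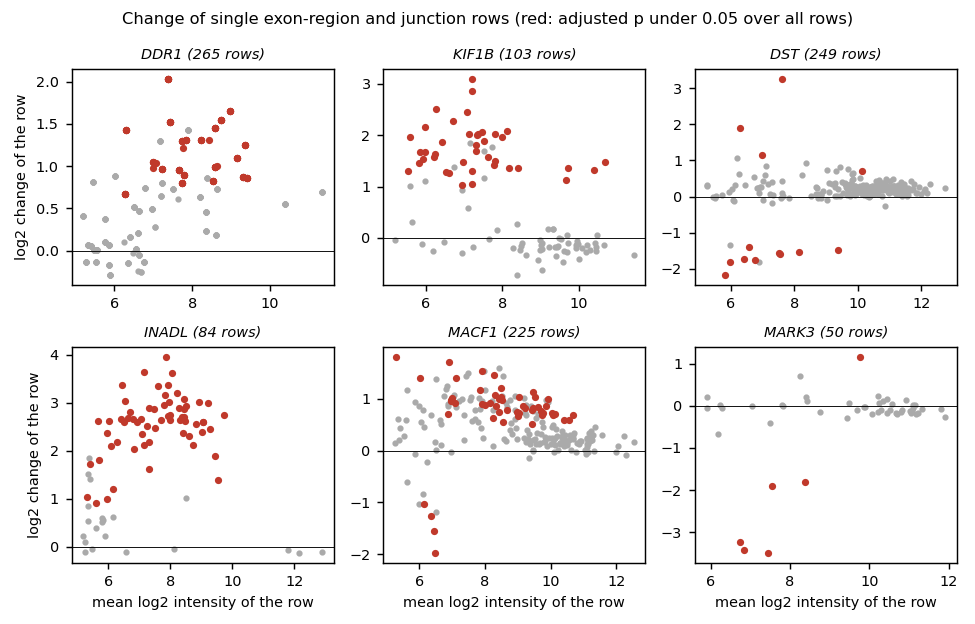
Log2 change of each exon region or junction against its mean log2 intensity over the 6 arrays, for the 6 genes with the smallest p in the F-test, with red points at an adjusted p under 0.05 over all rows. In DST 4 rows rose and 9 fell, while in INADL 63 of 84 rose.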

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

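The test of the arrays' control rows was chosen only after the data were examined; the signals below lie in data that the comparisons of genes do not use.

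Of the 213119 rows with no gene symbol 493 changed, 301 higher and 192 lower in doxycycline. The largest rises were those of PSR12027823.hg.1, from 5.89 to 10.23 (log2 change 4.34, adjusted p = 7.76e-04 in limma), and of PSR12027822.hg.1, from 6.39 to 10.57 (4.18, adjusted p = 6.25e-04). The row for MIR200C had a change of 4.57. Where both unnamed rows lie is not given in the sources used here, so whether they measure a gene of the cells or the induced construct was not determined. The largest falls were those of JUC07004641.hg.1, from 8.59 to 5.87 (adjusted p = 0.00122), and of PSR05032433.hg.1, from 8.48 to 6.25 (adjusted p = 0.00220). Of the 39483 rows with several symbols 209 changed, 113 higher and 96 lower. Among the arrays' own 75 control rows other than background and ERCC spike-ins, 4 passed, all lower in doxycycline, each with an adjusted p of 0.0491 over those rows: AFFX-r2-Bs-dap-3_at (log2 change -0.48), AFFX-r2-Bs-dap-5_at (-0.40), AFFX-r2-Bs-lys-5_at (-0.20) and AFFX-r2-Ec-bioC-5_at (-0.20). These are spike-in controls, and no biological explanation was tested for them.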

How the results depend on the processing

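The background covariate, the fit without untreated replicate B and treated replicate A, the rows above 8 and the own-variance test were chosen after the data were examined. The main counts were 2187 genes (1338 higher, 849 lower), 6729 rows, 1592 genes with uneven change and 19 lists. Genes numbered 29 (20 higher, 9 lower) at a fold of at least 2, 1061 (661 and 400) at an adjusted p under 0.01, and 696 (431 and 265; 643 shared with the main count) with the median over a gene's rows, which ended the calls of 41 named genes. With each array left out, genes ranged from 1307 (without treated replicate B) to 1895, those higher from 804 to 1098, those lower from 494 to 797, rows from 1614 to 3570 and lists from 17 to 19; without treated replicate C genes numbered 1398. Uneven genes then ranged from 644 (without treated replicate C) to 3863 (without treated replicate A), with 1008 without untreated replicate A and 830 without treated replicate B. They numbered 2632 with all rows, 2900 with Simes p, 3716 without untreated replicate B and treated replicate A, 369 with rows above 8 and 116 with own variances. Rows numbered 4223 with the background covariate and 1660 without both those arrays. With an estimated correlation 0 lists passed. The letters of the labels did not pair the cultures, since deviations correlated at -0.17 for A, -0.03 for B and 0.22 for C. No array correlated best with its own letter, although untreated C correlated about as well with treated C as with treated B (0.215 and 0.222). With the replicate block 1911 genes (1768 shared), 1202 rows, 1434 uneven genes and 19 lists passed. The cause of these differences was not tested. Of the 106 named genes past the threshold 92 passed without any single array, as did 14 of the 19 lists. Most named genes were chosen for large changes or small p in these data, so their share does not describe all genes. Of the 2187 genes 1263 were still called without treated replicate B and 1358 without treated replicate C. Over all alternatives for lists and named genes none reversed: for lists 431 values kept their side of the threshold, 44 lost it and 2 gained it, and for named genes 1547, 118 and 3. The lower mean lay in the background range in 726 changed genes, and both did in 557, of which 493 had a row above it. The seed-site alternatives were not run.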

Other observations

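The tests of ESRP-regulated exons, of both shares that changed in their mean, of bounds on the means that did not pass, of arrays with doxycycline alone and of the snoRNA mean per array, and the choice of snoRNA genes as a group, came only after the results they concern were seen.

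A part of the small nucleolar RNA genes, whose products guide the modification of ribosomal RNA, fell in doxycycline. Of all 238 such genes 39 fell and none rose, with a median log2 change of -0.10. Of the 76 with a mean above the background range 23 fell, with a median of -0.19 (limma camera p = 5.34e-13 at the preset correlation, and p = 0.146 with an estimated correlation). SNORA23 fell by 1.14 (from 10.32 to 9.19, adjusted p = 0.0281), SNORA21 fell by 0.91 (adjusted p = 0.00866) and SNORD114-28 fell by 0.76 (adjusted p = 1.81e-04), each on 1 row. A lower yield of small RNAs on the treated arrays may account for the fall: 61 other small-RNA genes above background had a median change of -0.15, with 9 lower and 1 higher. The snoRNA mean per array left a gap between the groups of 0.408 times the larger within-group range, so yield that varies from array to array may account for it as well, and no biological explanation was tested. The labelling kit named in the labels is one usual for microRNA arrays, and its effect on these rows was not tested.

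Several genes whose mean did not pass the test had single exon regions or junctions that changed strongly, here named after their values were seen. By the own-variance test 25 of its 116 genes did not pass in their mean. Of these 18, or 15.5% (95% interval 9.46 to 23.4) of the 116, had a 95% interval of the mean change within 0.2 of 0, more than the 5% of false calls allowed, but within 0.15 the share was 8.62% (4.21 to 15.3), which does not exceed it beyond its spread. FXR1, an RNA-binding protein gene, had a row change of -3.98 while its mean changed by -0.08, and ATP5C1, a subunit gene of ATP synthase, had one of -4.46 with a mean change of -0.01. TPM3 and OSBPL8, for a tropomyosin and a lipid transfer protein, had extreme row changes of -2.78 and 2.77.

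These own-variance values lean against uneven change only in genes that changed as a whole, and do not settle it: 78.4% (95% interval 69.9 to 85.5) of the 116 genes had changed in their mean. The share was 52.8% (50.3 to 55.2) of the 1592 genes of the F-test. That share cannot decide the question, since how many of those calls come from the pooled variance is not known. The pooled variance of the F-test may account for a part of its calls, of which 7.29% (6.06 to 8.68) were called with own variances. The own-variance test was simulated only for row changes of 2, so a call it missed need not come from the pooled variance. Compression of changes in dim rows stays open: of 1162 genes still testable with rows above 8, 27.8% (25.2 to 30.5) were called again. For the 116 genes of the own-variance test it was not tested. A split of untreated A and B and treated A against the others gave 3962 genes, so 2 of 10 splits gave as many as the real one, which points to a structure of the arrays other than the groups. The background rows of low GC content averaged 5.50, 5.69 and 5.57 on those arrays, and 5.40, 5.34 and 5.27 on the others. With that level as a covariate the F-test called 1310 genes, 948 of them among the 1592. Whether the level is that structure was not settled. With own variances 1 of 10 splits gave as many as the real one, with 116 genes and a highest other count of 0.

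A hypothesis is that part of the uneven change follows the rise of ESRP1. Of 25 genes known for ESRP-regulated exons 20 were tested and 11 were called by the F-test, against a median of 3 and a 95th percentile of 6 in 10000 random lists matched on rows (permutation p = 2.0e-04). With own variances 2 were called, NUMB and LRRFIP2 against a 95th percentile of 1 (permutation p = 0.0374). LRRFIP2 had an adjusted p of 0.0499 in that own-variance test, so this count rests on a call next to the threshold. Whether the changed rows of the called genes lie on the regulated exons was not tested. The fall of QKI, another splicing regulator, stays an untested alternative.

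For the interferon-stimulated genes, the arrays' background level as the whole cause is argued against by a median of -0.38 with that level as a covariate, against -0.37 without. Cultures that differ in these genes whatever their group stay a candidate explanation, since the gap between the groups was 0.728 times the larger within-group range, too near that range to decide. Doxycycline itself and the microRNA cannot be told apart, since 0 arrays had the drug without induction.

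Splits of the 6 arrays into 3 and 3 number 10, too few for a share under 0.05. For genes the real split alone gave as many, 1 of 10, with 2187 against a highest other count of 0, for rows 6729 against 0, and for lists 19 against 14. With the background level as a covariate 2178 genes changed, so that level is argued against as the cause of the main count.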
